A study of Mus musculus with 8 samples.

How the data were processed

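Messenger RNA was profiled in endothelial cells sorted by flow cytometry from the brains of mouse pups (C57BL/6) at postnatal day 6. The pups either lacked GLUT1 in endothelial cells (KO) or were wild type (WT), with 4 pups per group. Per the labels' protocols, cells were sorted directly into lysis buffer, stranded poly(A) libraries were prepared and single-end reads of 100 bp were sequenced at an intended depth of about 20 M reads (M for mega) per sample. The authors deposited 1 table of whole-number counts per gene for each library. The unit was read from the file headers and from the values, which were integers whose totals differed between libraries. Per the submitters' processing notes, STAR, featureCounts and the mouse build GRCm38 were used. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands could not be told apart.

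Each table held 25700 gene identifiers, of which 18602 had a count above 0 in at least 1 library. Gene symbols and coordinates came from GENCODE release M21 for GRCm38, which named 25587 of the identifiers. The other 113 took 0.0445% of the counts and stayed in the tests under their identifiers. Xist, Tsix, Hbb-b1, Hbb-b2 and Ahsp were fixed as list members but had no row and were not analysed here.

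Groups were taken from the genotype label of each sample. All data were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the genotype groups and its defaults (a minimum count of 10 and a minimum total of 15), which left 14154 genes. Libraries were scaled by TMM, with factors between 0.978 and 1.026. Genotype was the only term of the quasi-likelihood F test, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Levels are given as CPM (counts scaled to a library total of 1e6 by TMM), as mean ± SD over the 4 libraries of a group. The standard error of a log2 fold change was taken from the fold change and its F statistic. Log2 CPM values used a prior count of 2. Single values were compared with a two-sided exact permutation test over the 70 assignments of 4 libraries to each group, whose smallest possible p is 0.0286. A count of 0 allows up to 3 counts, or 0.144 CPM in the shallowest library and 0.0263 CPM in the deepest, and this limit covers counting error only.

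Before the data were examined, 41 gene lists were fixed for metabolism, stress, proliferation, vascular identity, other cell types, RNA quality and sex. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 41 lists. Camera with an estimated correlation and the rotation test fry were run beside it. Genes named in the text were chosen by a rule fixed at the same time. It took Slc2a1, the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 3 and no overlap between groups, up to 4 members with the smallest p from each biological list and up to 2 from each check list, and any called list member. Predicted, clone-named and sex-linked genes were left out of the 20 largest changes. Other genes named were chosen after their values were seen, and the text says so.

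The fit was tested on simulated counts drawn from the observed means, library sizes and dispersions. The changed genes were drawn only from genes with a mean log2 CPM above 3, so these shares do not hold for genes at lower levels. Of 199 changed genes among 13920, the fit called 86.9% of those changed by 2-fold and 54% of those changed by 1.5-fold. It also called 6 of 13700 unchanged genes. The list given a known shift was called, as was 1 list without one. Genes were drawn independently, with no cage effect or outlying library, so the simulation does not test lists whose members vary together.

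Alternatives fixed together with the lists changed the scaling (DESeq2 1.42.0 size factors, upper quartile), the filter, the test (DESeq2, limma-voom), the terms (cage, sex, pup number as a block, 1 surrogate variable from sva 3.50.0) and the libraries (each left out in turn). Further alternatives were chosen after seeing the data: leaving out KO pup 1 together with WT pup 2, thinning all libraries to the lowest total, and adding the microglial level as a term. Sex was not labelled and was read from the Y-linked genes for the sex term, which placed 2 pups with detected Y-linked genes in each group. Pairs of libraries were also checked for duplicates. The chi-square statistic per gene between any 2 libraries was at least 16.5, so no 2 libraries held the same counts.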

Results

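The data set compared brain endothelial cells of mouse pups lacking the glucose transporter GLUT1 in endothelium (KO, n = 4) with those of wild-type pups (WT, n = 4) at postnatal day 6. The comparison asked how the endothelial transcriptome differs when the main glucose transporter of the blood-brain barrier is lost. The total counts of KO pups 1 to 4 were 20.9, 24.2, 24.6 and 40.8 M (M for mega) and those of WT pups 5, 1, 2 and 3 were 25.9, 41.8, 114 and 36.2 M. KO pup 1 had the fewest detected genes, 13624, against 15756 to 17082 in the other libraries. Its log2 CPM values correlated with those of the other libraries at 0.913 to 0.932 across genes, whereas the others correlated at 0.958 to 0.981 with each other. By the sample titles, all 4 KO pups and WT pup 5 came from 1 cage and the remaining 3 WT pups from another. A second set of labels in the deposit places WT pup 3 rather than WT pup 5 in the cage of the KO pups, so genotype and cage were nearly confounded under either reading.

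The transcript of the targeted gene was lower in every KO pup than in every WT pup. Slc2a1 (ENSMUSG00000028645; GRCm38 chromosome 4, 119108711 to 119137983, plus strand), which encodes GLUT1, measured 1507 ± 89.6 CPM in KO and 3044 ± 664 CPM in WT (SD, n = 4 each). The KO level was 49.5% of the WT level, with a log2 fold change of -1.01 (SE 0.14, 95% interval -1.31 to -0.71) and an adjusted p of 0.00619 in edgeR's quasi-likelihood test. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 pups allow. Counts cover the whole gene and can include reads from exons outside a deleted part, so they do not measure the extent of deletion. With cage as a term, Slc2a1 stayed called under the cages of the titles (log2 fold change -1.31, adjusted p 0.0207) but not under those of the other labels (-0.89, adjusted p 0.331), nor with 1 surrogate variable as a term (-0.97, adjusted p 0.0683). Within the cage of the KO pups by title, which held 1 WT pup, the log2 fold change was also -1.31.

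Beyond Slc2a1, the largest rises among called genes with a mean log2 CPM of at least 3 included a cell-surface receptor, a nuclear receptor and a detoxifying enzyme. Eda2r, a receptor of the tumour necrosis factor receptor family, rose by 4.77 on the log2 scale (SE 0.38), from 0.868 ± 0.546 to 25.7 ± 2.57 CPM. Esr1, which encodes oestrogen receptor alpha, rose by 4.23 (SE 0.21), from 1.43 ± 0.419 to 26.7 ± 2.53 CPM. Phlda3, an inhibitor of Akt signalling, rose by 3.63 (SE 0.20), and Ephx1, the microsomal epoxide hydrolase, rose by 2.45 (SE 0.13). Log2 increases between 1.53 and 1.71 were measured for Gtse1, Dcxr, Spp1, Dglucy, Slc19a2 and Ccng1. Slc19a2 encodes a thiamine transporter, and Spp1 (osteopontin) was carried unevenly by the KO pups, from 17.4 CPM in pup 1 to 52.5 in pup 4. Spp1 was called by a narrow margin (edgeR adjusted p 0.0483) and in 11 of 22 alternative settings. Among the decreases, Fndc1 changed by -1.20 (SE 0.14), Kank1 by -0.89, the ectonucleotidase gene Enpp3 by -0.87, and Vwf, which encodes von Willebrand factor, by -0.85 (SE 0.10). Smaller decreases were measured for Hid1, Apod, Pfkp, Lef1 and Dynll1, between -0.63 and -0.57. Hid1 and Apod were each called in 10 of 22 alternative settings. In total, edgeR called 55 of 14154 genes, 39 higher and 16 lower in KO. Of these, 26 changed by at least 2-fold, 24 upward and 2 downward (Fndc1 and Slc2a1). None of the 55 overlapped between the groups, and over all genes 1018 (7.19%) did not overlap, where chance gives 2.86%.

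These counts rested in part on the test, on single libraries and on the cages. DESeq2 called 172 genes higher and 180 lower, and with no filter on low counts edgeR called 46 and 38, so the excess of higher over lower genes depended on the test and the filter. Without KO pup 1, the test called 60 genes higher and 25 lower, and without KO pup 1 and WT pup 2 together it called 50 and 26. Leaving out KO pup 2 gave 25 higher, leaving out KO pup 3 gave 6 lower, and leaving out WT pup 3 gave 27 lower. A cage term from the titles left 10 higher and 6 lower genes, 13 of them among the 55. Under the other cage labels 10 genes were higher and 0 lower, of which 9 were among the 55, with 758 genes at an unadjusted p under 0.05. Within the cage of the KO pups by title the counts were 10 higher and 12 lower. In these 3 fits the difference between genotypes rests on the single WT pup placed with the KO pups, whose spread is taken from the other libraries. All 55 genes kept the sign of their fold change in each of them, but this was fixed in advance. For all 55, every KO pup lay on the same side of every WT pup, so a comparison with 1 WT pup had to keep the sign.

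**Figure D1:**
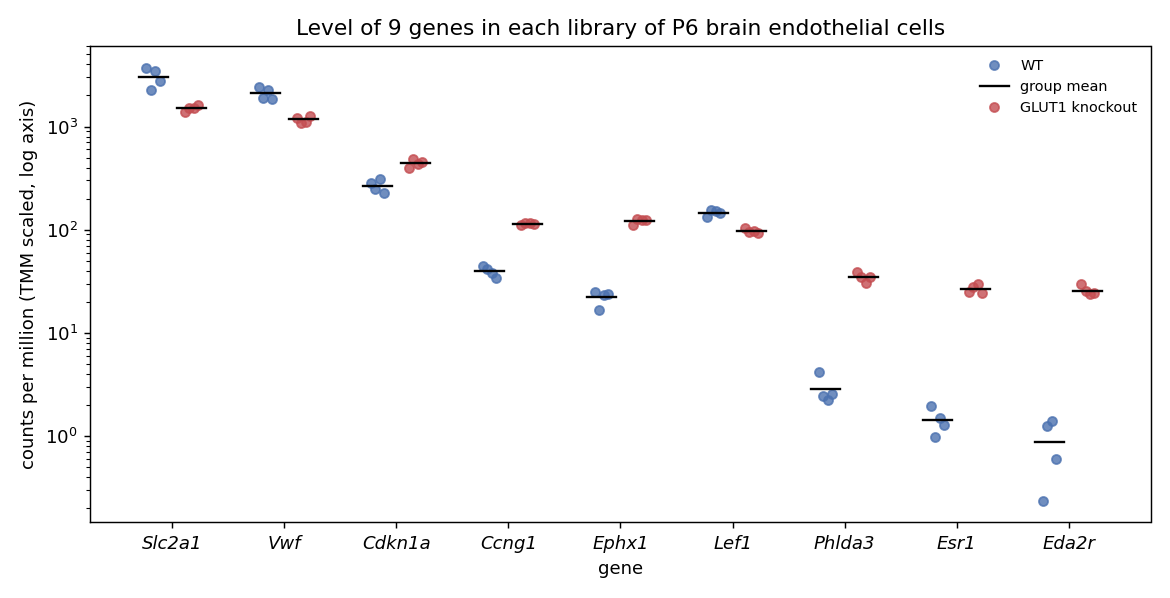
TMM-scaled CPM (log axis) of 9 genes in each of the 4 WT and 4 KO libraries, with points for pups and horizontal bars for group means. Slc2a1, Vwf and Lef1 lie lower in all 4 KO pups, and Cdkn1a, Ccng1, Ephx1, Phlda3, Esr1 and Eda2r lie higher in all 4.

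Targets of the transcription factor p53 formed the list with the clearest shift. Of its 12 members, 8 rose (Eda2r, Phlda3, Ccng1, Zmat3, Aen, Cdkn1a, Bax and Pmaip1) and none fell, while adjusted over the list alone 10 rose. The number called over all genes was 5 without KO pup 2 or without WT pup 1, and 4 with either cage term or within the cage of the KO pups by title. Ccng1 (cyclin G1) went from 39.5 ± 4.43 to 114 ± 1.97 CPM and Zmat3, an RNA-binding protein gene, from 34.7 ± 2.26 to 81.0 ± 5.42 CPM. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose 1.67-fold, from 266 ± 37.5 to 443 ± 39.9 CPM (adjusted p 0.0111). The apoptosis genes Bax and Pmaip1 rose 1.63-fold and 1.57-fold. Reads of Bax cannot be fully separated from those of the overlapping predicted gene Gm45808 on the same strand. Aen was called by a narrow margin (adjusted p 0.0427) and in 9 of 22 alternative settings, and Pmaip1 was called in 12 of 22. The mean log2 CPM of the list was 6.02 to 6.15 in KO pups and 4.69 to 4.95 in WT pups, and the median log2 fold change of its members was 0.72. Camera gave an adjusted p of 2.39e-63 with the preset correlation, and the adjusted p was 0.000202 with an estimated correlation and 2.76e-05 by fry. It was the single list called by all 3 tests. Under the cage terms its median was 0.75 by the titles (adjusted p 0.00413 with an estimated correlation) and 0.79 by the other labels (adjusted p 0.00354), and 0.75 within the cage of the KO pups by title (adjusted p 0.063).

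With the preset correlation, camera called 11 of the 41 lists, 7 higher and 4 lower, but 14 of the 35 possible splits of the libraries gave at least as many, so the 10 lists besides p53 targets are given as measured shifts. In the fits with a cage term and in those without 1 library, the p53 targets were the single list called with an estimated correlation, and within the cage of the KO pups by title 0 lists were. Among the metabolic lists, glycolysis was not called (median -0.02, adjusted p 0.204), but it was called lower without WT pup 2 (-0.06, adjusted p 0.0313) and with the second set of cage labels as a term (-0.07, adjusted p 0.0215). Those adjusted p values were 0.873 and 0.797 with an estimated correlation. One of its 21 tested members changed: Pfkp, the platelet-type phosphofructokinase, fell from 99.5 ± 4.91 to 65.5 ± 4.32 CPM (adjusted p 0.00467), although the antisense gene Pitrm1 overlaps it and the strand setting is not given. Bpgm (log2 fold change -0.25), Aldoc (0.90) and Gpi1 (0.15) did not pass. In the list of glucose and monocarboxylate transporters, Slc2a1 fell and Slc2a9, known as a urate transporter, rose 2.53-fold to 22.4 ± 2.27 CPM, with 9 of 11 members not passing (list median 0.28, adjusted p 0.284). Slc16a7 and Slc2a12 measured 0.60 and -1.12 on the log2 scale without passing. The 5 genes of the MondoA and ChREBP axis, which senses glucose phosphates, were called lower (median -0.28, adjusted p 0.0266, but 0.754 with an estimated correlation). Its members Arrdc4 and Txnip measured -0.97 (adjusted p 0.0917) and -0.39 (adjusted p 0.383), and none passed over all genes, while 1 fell adjusted over the list alone. Without KO pup 1, whose list mean was lowest, the median was -0.003 and the call was lost (adjusted p 0.193). The call was also lost without WT pup 5, where the median was -0.34 (adjusted p 0.0848), and with the second set of cage labels as a term (-0.16, adjusted p 0.35).

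Fatty acid oxidation was called higher by a small amount (median 0.06, adjusted p 0.029, but 0.463 with an estimated correlation). No single one of its 19 members passed, with Cpt1c at 1.12 (adjusted p 0.0737) and Acadl at 0.16. The list mean was nevertheless higher in every KO pup than in every WT pup (exact permutation p = 0.0286). Its call was lost without KO pup 1 (median 0.08, adjusted p 0.0748), KO pup 2 (0.04, adjusted p 0.0769), KO pup 3 (0.05, adjusted p 0.0516) or WT pup 1 (0.05, adjusted p 0.0798). It was also lost with a cage term by the titles (0.05, adjusted p 0.23) or by the other labels (0.07, adjusted p 0.257), while all these medians lay within 1.5 times of the median with all libraries. Cholesterol synthesis was also called higher (median 0.18, adjusted p 0.0302, but 0.754 with an estimated correlation), with 0 of 20 members passing and Nsdhl, Sc5d and Fdps at 0.30, 0.34 and 0.31. That call was lost without KO pup 1 (median 0.12, adjusted p 0.219), WT pup 5 (0.13, adjusted p 0.0848) or WT pup 3 (0.09, adjusted p 0.0842). The lists for the tricarboxylic acid cycle (median 0.03, adjusted p 0.328), nuclear oxidative phosphorylation (0.05, 0.13), the pentose phosphate pathway (0.06, 0.724), the hexosamine pathway (0.03, 0.724, with a mean of -0.07) and serine and one-carbon metabolism (0.08, 0.488) were not called, and none of their members passed over all genes. Adjusted over the list alone, 1 hexosamine gene rose and 2 fell. Nuclear oxidative phosphorylation was called higher without WT pup 3 (0.09, adjusted p 0.00593) and with the cage term from the titles (0.10, adjusted p 0.0195), with adjusted p values of 0.618 and 0.807 with an estimated correlation. Beside these lists, transcripts encoded by mitochondrial DNA, fixed as a check of RNA quality, took 2.28 ± 0.22% of counts in KO and 1.77 ± 0.12% in WT (exact permutation p = 0.0286). The share was highest in KO pup 1 (2.48%), the library with the fewest detected genes, and in KO pup 4 (2.46%). The list of these transcripts was called higher (median 0.41, adjusted p 9.02e-08, but 0.433 with an estimated correlation), with mt-Nd2 at 0.50 and mt-Nd1 at 0.41. None of its 7 tested members passed over all genes, while 6 did adjusted over the list alone.

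Venous genes were called lower as a list (median -0.27, adjusted p 1.68e-07, but 0.203 with an estimated correlation). Vwf fell from 2110 ± 286 to 1173 ± 85.9 CPM (adjusted p 0.00298), and adjusted over the list alone 4 of 12 members fell. The other 3 were Lcn2 (3.59 ± 1.42 CPM in KO, 14.5 ± 7.82 in WT), Nr2f2, a transcription factor of venous identity (log2 fold change -0.64), and the chemokine receptor Ackr1 (-1.11), none of which passed over all genes. The arterial and Notch list was called lower too (median -0.18, adjusted p 0.00201, but 0.754 with an estimated correlation). None of its 17 members passed over all genes, with Gja5, the gap junction protein connexin 40, at -1.33 (adjusted p 0.0826), Hey1 at -0.35 and Notch1 at -0.28. Adjusted over the list alone, 2 members fell. WT pups 5 and 2 stood highest for this list (means of 7.28 and 7.25), while WT pup 3 (6.97) lay within the range of the KO pups and WT pup 1 at its upper end (exact permutation p = 0.0857). WT pups 5 and 2 were also the highest for Gja5, Lcn2, Nr2f2 and Ackr1, and for the called genes Vwf, Slc2a1 and Fndc1. The list median was -0.02 with the second set of cage labels as a term (adjusted p 0.982). Vesicular transport and fenestration was called lower (median -0.28, adjusted p 0.00267, but 0.754 with an estimated correlation), with the caveolar genes Cavin1 at -0.37 and Cavin2 at -0.40. None of its 8 members passed over all genes, while 4 fell adjusted over the list alone. With the second set of cage labels its median was 0.00 and its call was lost (adjusted p 0.76). The Wnt and beta-catenin list missed the threshold (median -0.07, adjusted p 0.06), and Lef1, a transcription factor that acts with beta-catenin, was its 1 called member, falling from 146 ± 9.81 to 96.8 ± 4.58 CPM (adjusted p 0.00418). The list was called lower without KO pup 1 (adjusted p 0.0139), KO pup 2 (0.0368) or WT pup 2 (0.0313), with adjusted p values of 0.678, 0.815 and 0.879 with an estimated correlation. Axin2, a common readout of that pathway, measured 0.26 and did not pass.

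Barrier genes showed no list call. Junction genes had a median of -0.01 (adjusted p 0.819), with Cldn5 at -0.12 (SE 0.06), and barrier transporters a median of 0.03 (adjusted p 0.752), with Lrp8 at -0.34, Slco1a4 at 0.30 and Abcb1a at 0.27. No member of either list passed over all genes. Adjusted over the list alone, 1 of the 22 barrier transporters rose and 2 fell, while 0 junction genes changed. The tip cell list (median -0.12, adjusted p 0.13), basement membrane (0.10, 0.163) and pan-endothelial genes (-0.01, 0.724) were not called either. Of the 14 basement membrane genes, 1 fell adjusted over the list alone. Tip cell genes were called lower without KO pup 1 (-0.13, adjusted p 0.0463) or WT pup 2 (-0.17, adjusted p 0.00559) and within the cage of the KO pups by title (-0.13, adjusted p 0.00847). Those adjusted p values were 0.466, 0.452 and 0.571 with an estimated correlation. The proliferation lists were not called with all libraries and no cage term, with medians of 0.06 for G2/M and mitosis (adjusted p 0.344) and -0.02 for DNA replication and G1/S (adjusted p 0.819, with a mean of 0.01). Cdk1 and Ccna2 measured 0.15 and 0.19. WT pup 5 had the lowest WT mean of both lists, 4.76 against 5.11 to 5.31 and 4.39 against 4.69 to 4.99. The fit with the cage term from the titles and the fit within that cage both rest on this pup. With the cage term from the titles both lists were called higher, G2/M and mitosis at 0.40 (adjusted p 1.77e-08) and DNA replication and G1/S at 0.34 (adjusted p 1.13e-05), and both were called higher within the cage of the KO pups by title. For both lists the adjusted p was 0.549 with the term from the titles and an estimated correlation. With the second set of cage labels G2/M and mitosis was called lower (-0.16, adjusted p 0.0384), and it was called higher without KO pup 2 (0.18, adjusted p 0.000873) or WT pup 3 (0.16, adjusted p 0.0256). Those adjusted p values were 0.975, 0.815 and 0.853 with an estimated correlation.

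Among the remaining stress lists, the ATF4 and amino acid response was not called (median -0.03, mean 0.00, adjusted p 0.911). Sesn2, a stress-induced inhibitor of mTORC1 signalling, was its single called member of 27, rising 1.85-fold (adjusted p 0.0318). It was called in 11 of 22 alternative settings. Gdf15 measured 1.09 without passing. Neither hypoxia response (median 0.06, mean -0.07, adjusted p 0.923), endoplasmic reticulum chaperones (0.03, 0.565), autophagy (0.01, 0.724), endothelial inflammation (-0.22, 0.13) nor the immediate early and dissociation response (0.13, 0.324) was called. The immediate early and dissociation response was called higher with the second set of cage labels as a term (0.97, adjusted p 1.17e-23), within the cage of the KO pups by title (0.31, adjusted p 0.0246) and without KO pup 1 (0.25, adjusted p 0.0383) or WT pup 2 (0.39, adjusted p 0.00017). Those adjusted p values were 0.396, 0.866, 0.898 and 0.879 with an estimated correlation, and WT pup 3, on which the second set of cage labels rests, had the lowest mean of this list. With the second set of cage labels ATF4 and amino acid response (0.11, adjusted p 0.0411) and endoplasmic reticulum chaperones (0.11, adjusted p 0.0384) were called higher and endothelial inflammation turned to 0.52 (adjusted p 0.0215), while without WT pup 3 endothelial inflammation was called lower (-0.32, adjusted p 0.00121). With an estimated correlation these adjusted p values were 0.396, 0.762, 0.799 and 0.618. Vegfa measured -0.56 and Fos 0.43, both below the threshold. The interferon response was called higher (median 0.20, adjusted p 0.029, but 0.838 with an estimated correlation), with Rsad2 at 1.22 and Cxcl10 at 0.99 and 0 of 19 members passing. The list means overlapped (exact permutation p = 0.486). Against WT pup 5 alone, the 1 WT pup in the cage of the KO pups by title and the one with the highest WT mean (4.89 against 3.74 to 4.31), the median was -0.32. The call was lost without KO pup 3 (0.19, adjusted p 0.0598), KO pup 4 (-0.02, adjusted p 0.679), WT pup 1 (0.12, adjusted p 0.0798) or WT pup 3 (0.03, adjusted p 0.491). Among KO pups, pups 3 and 4 had the highest means of both this list and the microglia and macrophage list, and with the microglial level as a term, chosen after seeing the data, the interferon median was 0.01 (adjusted p 0.247).

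**Figure D2:**
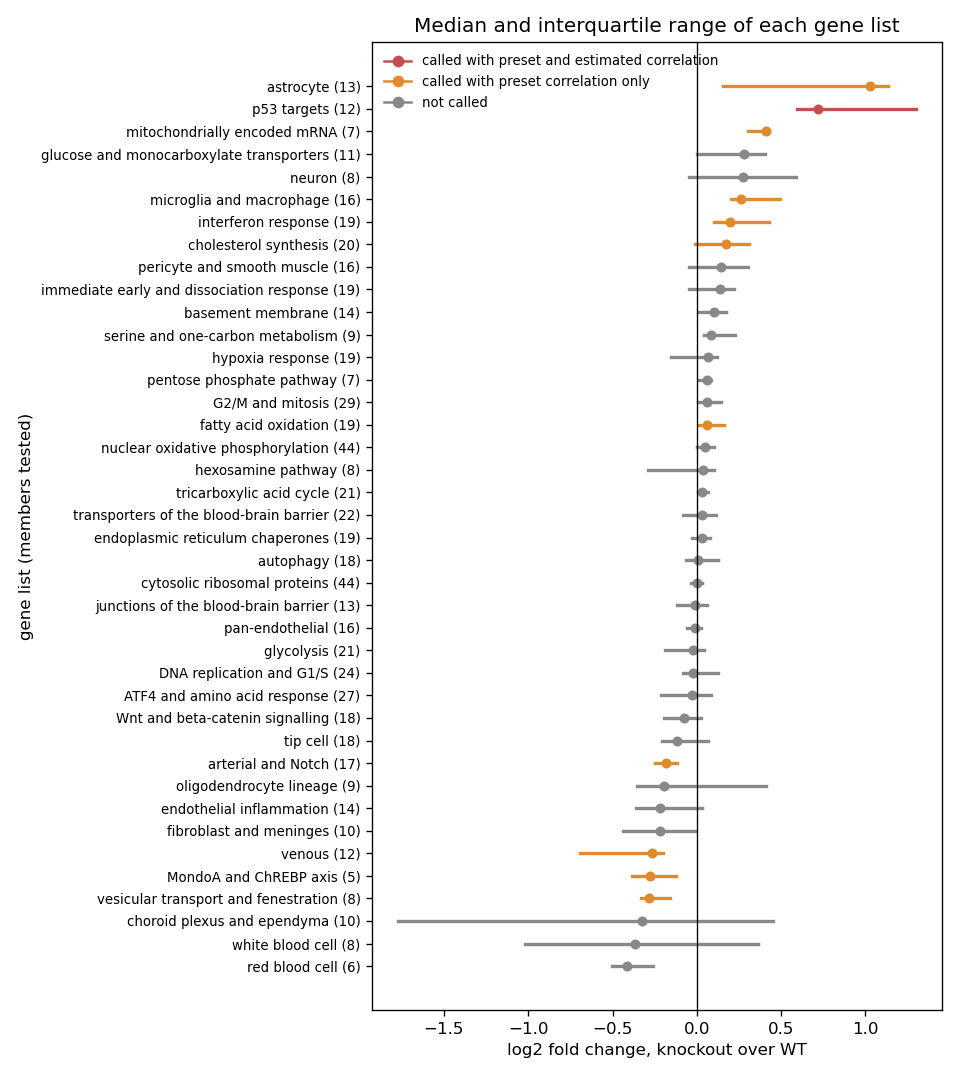
Median (points) and interquartile range (bars) of the log2 fold change, knockout over WT, for 40 gene lists, with the number of tested members in brackets and the sex-linked list left out. The p53 targets (median 0.72) are the list called with both the preset and the estimated correlation, 10 lists are called with the preset correlation alone, and 29 are not called.

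Markers of other cell types were detected, and those of astrocytes and of microglia and macrophages were called higher as lists. Astrocyte markers were called higher as a list (median 1.03, adjusted p 0.00167, but 0.823 with an estimated correlation), with Fabp7 at 9.82 ± 3.06 CPM in WT and 22.3 ± 7.19 in KO and Gfap at 14.6 ± 7.61 and 38.9 ± 20.0 CPM. Adjusted over the list alone, 4 of 13 members rose. KO pups 2 and 4 had list means of 4.24 and 4.22, while KO pups 1 and 3 (3.26 and 3.04) lay within the WT range of 2.28 to 3.55 (exact permutation p = 0.257). No astrocyte gene passed over all genes, and the call was lost without KO pup 4 (median 0.89, adjusted p 0.054) and with a cage term by the titles (0.50, adjusted p 0.526) or by the other labels (0.36, adjusted p 0.35). Microglia and macrophage markers were called higher (median 0.26, adjusted p 0.0118, but 0.823 with an estimated correlation), all 16 with a positive fold change and none passing, among them Mrc1 at 0.77 and Tyrobp at 0.51. Their list mean in KO ran from 5.12 in pup 1 to 6.67 in pup 3, against 5.14 to 6.03 in WT (exact permutation p = 0.543). The call was lost without KO pup 3 (median 0.03, adjusted p 0.493), KO pup 4 (0.17, adjusted p 0.0849) or WT pup 2 (0.14, adjusted p 0.209). It was also lost with the cage term from the titles, where the median was -0.01 (adjusted p 0.977), and with the second set of cage labels, where the median stayed at 0.26 (adjusted p 0.257). Lists for pericytes and smooth muscle (median 0.14, adjusted p 0.0912), neurons (0.27, 0.514), the oligodendrocyte lineage (-0.19, 0.932, with a mean of 0.11), red blood cells (-0.41, 0.139), white blood cells (-0.37, 0.328), fibroblasts and meninges (-0.22, 0.13) and choroid plexus and ependyma (-0.33, 0.13) were not called. With the cage term from the titles red blood cells (-1.05, adjusted p 2.74e-08), fibroblasts and meninges (-0.68, adjusted p 0.000317) and choroid plexus and ependyma (-1.27, adjusted p 4.23e-05) were called lower, with adjusted p values of 0.527, 0.549 and 0.549 with an estimated correlation. With the second set of cage labels red blood cells (-0.52, adjusted p 0.0279) and pericytes and smooth muscle (-0.48, adjusted p 0.0223) were called lower, with adjusted p values of 0.799 and 0.975 with an estimated correlation. Without WT pup 2 red blood cells (-0.67, adjusted p 1.3e-05) and fibroblasts and meninges (-0.16, adjusted p 0.0464) were called lower, and without KO pup 4 fibroblasts and meninges (-0.47, adjusted p 0.00405) and choroid plexus and ependyma (-1.03, adjusted p 0.0036), with adjusted p values of 0.452, 0.921, 0.756 and 0.517 with an estimated correlation. Pericytes and smooth muscle were called higher without KO pup 3 (0.24, adjusted p 0.00672), WT pup 5 (0.32, adjusted p 0.00552) or WT pup 3 (0.50, adjusted p 0.000259), with adjusted p values of 0.897, 0.941 and 0.735 with an estimated correlation. Ttr, the abundant choroid plexus transcript, measured 121 ± 113 CPM in KO and 866 ± 675 CPM in WT, and did not pass (adjusted p 0.193). Cytosolic ribosomal protein genes (median 0.00, adjusted p 0.923) and Y-linked genes (0.15, 0.923) were not called, except the Y-linked genes with the second set of cage labels as a term (adjusted p 0.0451, but 0.799 with an estimated correlation).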

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

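Among the tests below, the one on KO pup 1 for the p53 targets, the one on dissociation and the one on Cre recombinase were chosen only after the p53 result was seen, as was leaving out KO pup 1 with WT pup 2. Of 108 groups of 4 libraries examined, 7 held a library far from the other 3, where chance gives 5.4. In KO, pup 1 had 13624 detected genes against 15866 to 16327 in the others (gap over range 0.8294). Among WT libraries, pup 5 stood apart for Phlda3 (4.14 CPM against 2.24 to 2.55, 0.8384) and pup 1 for Ephx1 (16.6 CPM against 23.5 to 24.8, 0.8405). WT pup 1 also stood apart for Dcxr (8.46 CPM against 4.90 to 5.45, 0.8452). WT pup 5 did so for Gria3, a glutamate receptor gene called higher in KO and chosen after its values were seen (1.66 CPM against 0.405 to 0.574, 0.8651). Gria3 was called in 11 of 22 alternative settings. The mean log2 CPM of the cholesterol synthesis list was high in KO pup 1 (4.09 against 3.87 to 3.89, 0.8788) and in WT pup 1 (3.95 against 3.70 to 3.73, 0.908).

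The number of called genes was not matched by any other division of the libraries. The real split gave 55 genes and the highest of the other splits 6, so 1 of 35 splits gave as many, the smallest number possible. All other splits mix KO and WT pups, and the real split is nearly that of the cages. The splits therefore cannot exclude chance as the source of the called genes. For changes of at least 2-fold the values were 26 and 5, again 1 of 35. The number of called lists was different: 14 of 35 splits gave at least the 11 lists of the real one, with 17 at most, so chance cannot be excluded for that number either. For the p53 list median, 0.72 in the real split against 0.49 in the highest other, 1 of 35 splits reached the value.

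The rise of p53 targets was weighed first. The list mean was 6.02 in KO pup 1, the lowest of the KO pups, and 6.06 to 6.15 in the others. The rise was thus present without KO pup 1 (median 0.757), which argues against that library as the cause. With the cage terms the median was at least 0.75. Every WT pup lay below every KO pup, so the rise had to remain in those fits. The list means of WT pups 5 and 3, the candidates for the cage of the KO pups, were 4.7 and 4.69. Those of WT pups 1 and 2 were 4.76 and 4.95. Under either reading the WT pup in that cage stood at the WT level. This argues against the cages as the cause, as far as 1 pup can. Stress of dissociation was weighed next. With all libraries the upper 95% bootstrap bound of the median of the immediate early and dissociation list was 0.186. That bound came from resampling the 19 genes of the list rather than the pups, so it does not cover the spread between animals. Of the WT pups, 3 had a higher mean for that list (8.3, 8.48 and 8.95) than KO pup 1 (8.05). The p53 targets of KO pup 1 were nevertheless at the KO level. WT pup 2 had the highest mean of all libraries (8.95, against at most 8.81 in KO). Its p53 list mean was 4.95, against at least 6.02 in KO. These values argue against dissociation stress as the cause, as far as this list measures it. But the median was 0.386 without WT pup 2, 0.249 without KO pup 1 and 0.477 without both. It was 0.975 with the second set of cage labels, a fit that rests on WT pup 3, which had the lowest list mean. None of these calls held with an estimated correlation (adjusted p 0.396 or higher). Cre recombinase present only in the knockout cells may also raise p53 targets through DNA damage, and this stays open. The labels do not say which pups carried Cre. The Esr1 count, at the KO level in 0 of 4 WT libraries, is not a known marker of it. Loss of GLUT1 is the biological explanation the design gives, and it was not tested against these.

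Esr1 rose 18.8-fold to a nearly equal level in all 4 KO pups (24.4 to 29.6 CPM). A candidate explanation is that reads of a Cre-ERT2 transgene, which carries a part of the oestrogen receptor, were counted at Esr1; the Cre driver is not given in the sources used here. The 11 tested oestrogen receptor targets had a median log2 fold change of -0.002, but a receptor need not be active, and members going both ways decide nothing. Counts per gene do not show where in Esr1 the reads lie, so a transgene and a true induction cannot be told apart.

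Microglia and macrophage transcripts were weighed last. KO pup 1 had the lowest list mean of the 8 libraries (5.12), which argues against that library as the cause of the rise, and leaving it out, which could only raise the list median, gave 0.531. A larger share of unchanged microglia in the sort would raise homeostatic and activated genes alike. The activated set lay below the homeostatic set in all 8 libraries, on average by 0.276 less in KO than in WT on the log2 scale, with overlapping groups (exact permutation p = 0.429), which is consistent with such a share, though with 4 pups per group a change of state of this size is not excluded either. The cages stay open, since the list median was -0.011 with the cage term from the titles but 0.263 with the second set of cage labels, and the call was absent with an estimated correlation.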

How the results depend on the processing

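Chosen after seeing the data were 3 alternatives: leaving out KO pup 1 with WT pup 2, thinning counts to the lowest total, and a microglial term. Against 39 higher and 16 lower genes, 26 by at least 2-fold, the counts moved by more than 1.5 times as follows. DESeq2's test called 172 higher and 180 lower, and all 55 genes were among these calls. Of its calls, 102 changed by at least 2-fold. The cage term from the titles gave 10 and 6, with 16 by 2-fold, the second set of cage labels 10 and 0, with 10 by 2-fold, and the cage of the KO pups by title alone 10 higher. With no filter 38 were lower, with 1 surrogate variable 4, and without KO pup 1 and WT pup 2 26. Leaving out 1 library at a time gave 25 to 60 higher, 6 to 27 lower, 19 to 37 by 2-fold, 9 to 16 lists and a Slc2a1 log2 fold change of -1.14 to -0.91. Slc2a1 kept its direction and was not called with the second cage labels (-0.89), with 1 surrogate variable (-0.97, adjusted p 0.0683) or with pup number as a block. Lists called went from 11 to 17 within the cage of the KO pups by title, to 1 with an estimated correlation and to 1 by fry. The cage fits rest on 1 WT pup. The cause of the other changes was not tested.

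Pup numbers 1 to 3 recur in both groups but are not stated to pair pups, and same-numbered pups did not deviate together (correlations -0.03, 0.03 and -0.07; 0 of 3 correlated best with its own number). With the number as a block, 11 genes were higher and 0 lower, 956 having an unadjusted p under 0.05, 11 changed by 2-fold and Slc2a1 measured -0.91 without a call (adjusted p 0.0931). Under this block 4 p53 targets were called and the list had an adjusted p of 0.134 with an estimated correlation.

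The p53 list was called in all 22 settings in which the lists were followed, 20 of them by camera with the preset correlation (median 0.67 to 0.86). With an estimated correlation it lost its call within the cage of the KO pups by title (adjusted p 0.063) and with pup number as a block. Of 39 other called genes named or followed, none changed sign, which the lack of overlap between the groups made likely in advance. Of the 39, 8 (Ccng1, Dglucy, Eda2r, Ephx1, Esr1, Phlda3, Ppef1, Zmat3) were called in all 22 settings, Ppef1 being chosen after its values were seen. Of 902 list values, 792 kept their side, 52 lost and 50 gained a call. Turned were, with the cage term from the titles, interferon response (-0.323) and microglia and macrophage (-0.011), with the second cage labels endothelial inflammation (0.522), G2/M and mitosis (-0.159), arterial and Notch by camera (-0.016) and pericyte and smooth muscle (-0.477), and within the cage of the KO pups by title interferon response (-0.323) and pericyte and smooth muscle (-0.205). At 20.9 M counts, 0 counts allow up to 0.144 CPM.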

Other observations

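Of the 55 called genes, 41 lay outside the fixed lists, and those named here were chosen after their values were seen. Ei24 and Rps27l, both described as p53-inducible, rose 1.49-fold and 1.51-fold, and Ercc5, a nuclease of nucleotide excision repair, rose 1.56-fold. Zfp365 rose 8.5-fold from 1.31 ± 0.449 CPM in WT (SD, n = 4). Bcl2, which opposes apoptosis, fell from 44.5 ± 3.05 to 30.3 ± 2.89 CPM, with an edgeR adjusted p of 0.0427 and a call in 9 of 22 alternative settings.

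Ecm1, Mmrn2 and Pros1 were also chosen after their values were seen. Ecm1 rose 2.23-fold to 473 ± 76.1 CPM, Mmrn2, an endothelial extracellular matrix protein gene, rose 1.46-fold to 495 ± 13.4 CPM, and Pros1, which encodes the anticoagulant protein S, rose 1.41-fold. Of 255 tested solute carrier genes, edgeR called 3, which were Slc2a1, Slc2a9 and Slc19a2. Without KO pup 1, the leukocyte genes Cd53, Ptprc and Cd86 were called higher by 1.08, 0.95 and 0.93 on the log2 scale (adjusted p 0.0132, 0.0217 and 0.0184), along with the p53 target Mdm2 (0.49, adjusted p 0.0453). None of these 4 was called with all libraries. Among KO pups, Ptprc was lowest in pup 1 (16.4 CPM against at least 27.8), so leaving that pup out could only raise the difference. The mean of the microglia and macrophage list ranked the KO pups in the same order as Ptprc. Both were lowest in pup 1 (list mean 5.12) and highest in pup 3 (6.67, with Ptprc at 36.7 CPM). Whether these calls reflect the microglial share of the sort was not tested. The white blood cell list, which holds Ptprc, had a lower mean log2 CPM in every KO pup than in every WT pup. The means were 1.24 ± 0.18 in KO and 1.87 ± 0.25 in WT (exact permutation p = 0.0286), without a list call. Of its 8 tested members, 5 measured lower and 3, Ptprc included, higher.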
